A study of Homo sapiens with 3 samples.

How the data were processed

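The series measured MYC binding by single-read ChIP-seq in P493 cells, with 1 untreated MYC library, 1 MST-312 MYC library and 1 input library. The dose and duration of MST-312 are not given in the sources used here. A peak list was analysed for each MYC library; the input enters only as the background against which both lists were called. Conditions were taken from the treatment labels.

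Reads were processed with CASAVA 1.8 and Bowtie2 2.2.3 on hg19, per the submitters' processing notes. Peaks were called separately in each library with MACS 2.0.10.20131216, per the file headers, with the same input as control, a fragment length of 200 bp without a model, a p-value threshold of 0.05, at most 3 duplicate tags per position, and a local background over 1000 and 10000 bp. The tag size was 35 bp, and the genome size was set to 3095677412 bp. The deposited pileup is a signal value, the number of extended fragments at the summit; per the file headers the larger data set was scaled to the smaller, and since both MYC libraries kept fewer tags (60805153 and 55400354) than the input (63069522), their pileups are unscaled. The deposited fold enrichment is a ratio of the pileup to the local background from the input, and its values fit 1 being added to both terms. The deposited −log10 p and −log10 q values carry column names without the minus sign. The file headers say that q would not be calculated, yet the column holds values, the lowest being 13.01 in the untreated and 13.02 in the MST-312 list. The authors' lists therefore hold only strong calls, under a filter that the headers do not state: peak numbers run to 695490 in the untreated and 777551 in the MST-312 list, against 31378 and 27614 listed peaks. A site missing from a list may thus still have been called at a lower level. The smallest local background back-calculated as (pileup + 1) / fold enrichment − 1 was 3.93 and 3.58 fragments, the kept tags times 200 bp over the genome size to within 8.7e-05%.

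Coordinates are 1-based hg19 positions as listed. No rows within a list shared bases, so each listed peak is a region. A region had a partner when it shared at least 1 bp with a region of the other list. Shares carry exact Clopper-Pearson 95% intervals (scipy 1.17.1), which cover counting error over regions and not the spread between libraries; tags without molecular identifiers are not independent molecules. Chance overlap came from 100 random placements of the MST-312 regions on their own chromosomes, between the outermost listed positions. Fold enrichment, −log10 q and pileup were used to describe, rank or filter regions within their own list. With 1 library per condition no test between conditions was run. Overlap was computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and checked against bedtools 2.31.1, which gave the same 16803 overlapping untreated regions. A simulated second list copied a known share of the 31378 untreated regions per strength part, with shifts too small to break an overlap. The recovered shares differed from the true ones by at most 0.0637 percentage points. This checks the code only, and not how well 1 bp of overlap finds shared sites whose widths or summits differ. Figures were drawn with matplotlib 3.10.9.

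Overlap rules, ranking measures, the named-region rule and most alternatives were fixed before the data were examined. The named regions are the 8 with the highest fold enrichment among untreated regions with a partner, untreated regions without a partner and MST-312 regions without a partner. Alternatives covered the overlap rule, the strength threshold, lists of equal length, the set of chromosomes, the measure of strength and the merging of nearby rows. A threshold of −log10 q of at least 10, chosen before the data were examined, removes no listed region. A threshold of 26 (double the lowest listed value), a 1 kb gap and the removal of regions with local background over 3 times the list median were added after seeing the data. Assignment of regions to genes, gene groups, promoters and E-box sequences was planned and not carried out, since no hg19 annotation or sequence was used here.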

Results

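MYC occupancy was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in P493, a human B cell line that carries a repressible MYC gene. The transcription factor MYC was precipitated with the N262 antibody from untreated cells and from cells given MST-312, a small-molecule telomerase inhibitor. The design asked how MST-312 changes the set of genomic sites bound by MYC. The series holds 3 samples, which are an untreated MYC ChIP library, an MST-312 MYC ChIP library and an input library of untreated cells. Each condition is a single library, so no difference between them has a replicate check, and no p-value for the effect of treatment can be given. The untreated library had 80489246 tags, of which 60805153 (75.5%) were kept after limiting duplicates. The MST-312 library had 108838301 tags, of which 55400354 (50.9%) were kept. The redundant rate was 0.24 in the untreated library, 0.49 in the MST-312 library and 0.01 in the input. All intervals below are exact Clopper-Pearson 95% intervals and cover counting error over regions only.

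MYC-bound regions were fewer and narrower in the MST-312 list. The untreated list held 31378 regions covering 26.97 Mb of hg19, with a median width of 678 bp (quartiles 413 and 1131 bp). The MST-312 list held 27614 regions covering 19.71 Mb, with a median width of 566 bp (quartiles 375 and 913 bp). The MST-312 list was thus 12.0% shorter in regions and 26.9% shorter in covered length, and its library kept 8.89% fewer tags. These differences depend on the threshold: at −log10 q of at least 26 the lists held 16909 and 11506 regions (32.0% fewer) and covered 19.5 and 11.5 Mb (41.1% less). The authors' fold enrichment over local background had a median of 6.83 in the untreated list (quartiles 5.51 and 10.6) and of 6.55 in the MST-312 list (quartiles 5.61 and 8.53). The highest fold enrichment was 110.6 in the untreated list and 77.8 in the MST-312 list. These fold values belong to each list and were not used as a measure of change. Regions were fewer in the MST-312 list on 20 of the 23 chromosomes compared (1 to 22 and X) and more numerous on chromosomes 4, 18 and 21.

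The second comparison asked which MYC regions of untreated cells were also called after MST-312. Of the 31378 untreated regions, 16803 shared at least 1 bp with an MST-312 region, which is 53.6% (95% interval 53.0 to 54.1). The other 14575 untreated regions had no partner. Conversely, 17493 of the 27614 MST-312 regions shared bases with an untreated region (63.3%, 62.8 to 63.9), and 10121 had no partner. When the MST-312 regions were placed at random on the same chromosomes, 1.71% of untreated regions were overlapped on average, and 1.92% in the highest of 100 placements. Both lists were called against the same input library, so part of the shared calls could arise from that input, and the random placements do not include this. Placement was also uniform along each chromosome. The 1.71% therefore does not allow for gaps in the assembly or for parts of the genome where listed regions gather. With summits required to lie within 100 bp, the shares were 39.3% of untreated and 44.7% of MST-312 regions. With −log10 q of at least 26 in the list asked about, they were 82.0% and 95.4%.

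The MYC regions with the highest fold enrichment were called in both libraries. All 100 untreated regions with the highest fold enrichment, and all 1000, had an MST-312 partner. In the MST-312 list the corresponding numbers with an untreated partner were 100 of 100 and 999 of 1000. In the strongest of 10 equal parts of the untreated list (3137 regions), 9 had no partner when ranked by fold enrichment, 5 by −log10 q and 11 by pileup. The untreated region with the highest fold enrichment lay on chromosome 13 at 91999046 to 92002032, with a summit pileup of 600 fragments and a fold enrichment of 110.6. Its MST-312 partner (91999148 to 92001957) was also the highest of its own list, with a pileup of 391 fragments and a fold enrichment of 77.8, and the summits lay 33 bp apart. The next untreated regions were on chromosome 14 at 91882991 to 91885594 (fold enrichment 94.9), whose partner ranked 3rd in the MST-312 list, and on chromosome 19 at 1861649 to 1865209 (fold enrichment 84.5), whose partner ranked 16th. Chromosome 7 held the regions at 6047918 to 6049455 (75.9) and 22893213 to 22894974 (74.6), whose partners ranked 8th and 2nd. The remaining members of the leading 8 were on chromosome 17 at 49230551 to 49231993 (70.9) and 7209977 to 7212604 (69.9), and on chromosome 13 at 31037913 to 31039448 (70.2).

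Among 15265 pairs in which a single untreated region met a single MST-312 region, the summits lay a median of 46 bp apart, and 74.7% lay within 100 bp. In these pairs the untreated regions had a median width of 998 bp and a median summit pileup of 99 fragments (quartiles 66 and 152). The MST-312 regions of the same pairs had a median width of 773 bp and a median pileup of 67 fragments (quartiles 50 and 96). The local background at these summits, back-calculated from the pileup and the fold enrichment, had medians of 8.68 and 7.91 fragments. Over the strongest of 10 equal parts of the pairs by untreated fold enrichment, the median pileup was 266 fragments in the untreated list and 154 in the MST-312 list. This choice of pairs favours high untreated pileups; over the strongest part by MST-312 fold enrichment instead, the medians were 243 and 160. Pileups were unscaled in both libraries, which kept 60805153 and 55400354 tags, and the sources used here name no spike-in. The values stand side by side and no ratio was tested. A single untreated region was split over 2 or more MST-312 regions in 961 cases, and 335 MST-312 regions spanned 2 or more untreated ones.

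The share of MYC regions called in both libraries depended on their strength within their own list. Untreated regions were ranked by fold enrichment and divided into 10 equal parts. In the weakest part (fold enrichment 2.01 to 4.79), 25.7% had an MST-312 partner (24.1 to 27.2). The share was 24.6% in part 2, lowest at 22.5% (21.0 to 24.0) in part 3 and 24.2% in part 4. It was 32.8% in part 5, 52.1% in part 6, 71.3% in part 7 and 86.3% in part 8. It reached 96.4% in part 9 and 99.7% (99.5 to 99.9) in the strongest part, with fold enrichment from 16.8 to 110.6. In the MST-312 list the share with an untreated partner was lowest in part 5, at 37.0% (35.2 to 38.8), and 99.4% in the strongest part. The weakest part of the MST-312 list by fold enrichment had a share of 70.1%. Ranked by −log10 q instead, the MST-312 shares went from 18.9% in the weakest part to 99.9% in the strongest, and the untreated shares from 10.5% to 99.8%.

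**Figure D1:**
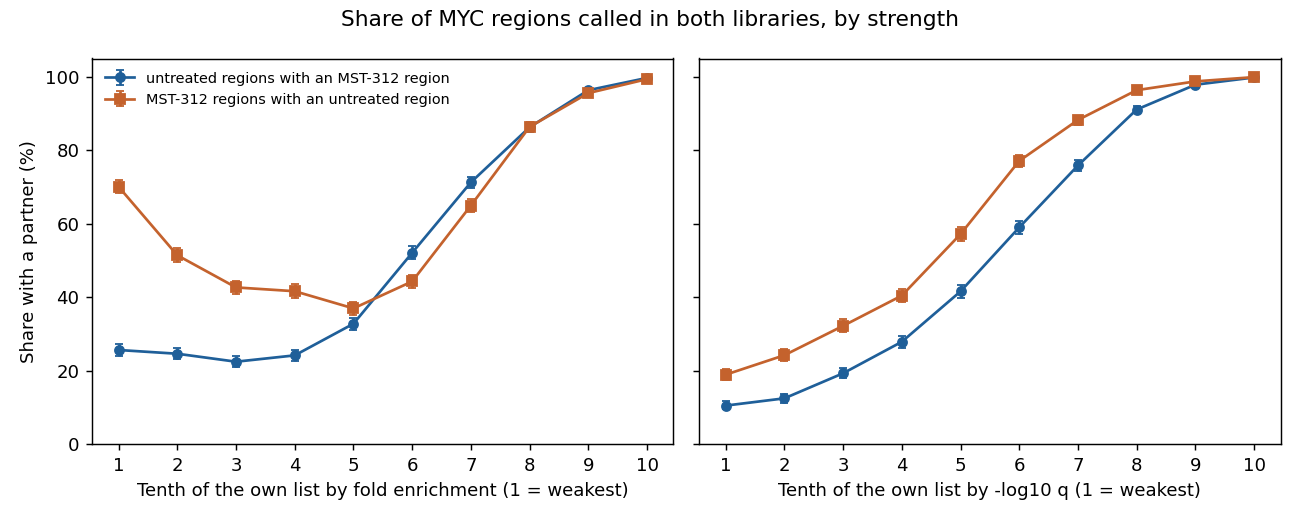
Share of regions (%) with a partner in the other list, for 10 equal parts of each list ranked by the authors' fold enrichment (left) or −log10 q (right); blue circles are untreated regions, orange squares MST-312 regions, and bars are exact 95% intervals over regions. The strongest part is above 99% in both lists and rankings, while the weakest part by −log10 q lies at 10.5% for untreated and 18.9% for MST-312 regions.

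Broad MYC regions were called in both libraries more often than narrow ones. Of the 1607 untreated regions of at least 2000 bp, 98.1% (97.3 to 98.7) had an MST-312 partner, against 9.12% (7.89 to 10.5) of the 1962 regions under 300 bp. Of the 543 MST-312 regions of at least 2000 bp, all 543 had an untreated partner, against 16.0% (14.5 to 17.5) of the 2282 regions under 300 bp. Width also rose with strength. From the weakest to the strongest of 10 parts by −log10 q, the median width went from 376 to 1497 bp in the untreated list. In the MST-312 list it went from 361 to 1181 bp. Widths were not compared at equal strength, so the 2 traits cannot be told apart here. Untreated regions without a partner had a median width of 438 bp and a median −log10 q of 17.4 (quartiles 14.7 and 24.1). Untreated regions with a partner had medians of 1026 bp and 62.6 (quartiles 33.0 and 118.1). The MST-312 regions without a partner had medians of 368 bp and 15.4 (quartiles 13.9 and 18.1), close to the lowest listed value of 13.02. Together the untreated regions without a partner covered 7.71 Mb, and the MST-312 regions without a partner covered 4.24 Mb.

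Some strong untreated MYC regions had no MST-312 partner. The strongest by fold enrichment lay on chromosome 9 at 4792186 to 4794235, with a pileup of 463 fragments, a fold enrichment of 22.9 and a −log10 q of 444.6; the nearest MST-312 region was 50.2 kb away. The next lay on chromosome 15 at 55790290 to 55791545 (fold enrichment 20.1, pileup 174), chromosome 3 at 151256618 to 151257330 (19.6, pileup 111) and chromosome 21 at 47742315 to 47745522 (19.3, pileup 129). Their nearest MST-312 regions were 27.2, 45.1 and 32.2 kb away. On chromosome 1, the region at 183439255 to 183439655 (fold enrichment 18.1) had an MST-312 region 336 bp away, so that its lack of a partner depends on the overlap rule. The remaining 3 of these 8 were on chromosome 19 at 52799988 to 52801020 (17.6), chromosome 17 at 74178050 to 74178687 (17.2) and chromosome 12 at 31789539 to 31790240 (17.2).

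Some MST-312 regions had no untreated partner. The 8 with the highest fold enrichment had widths from 380 to 744 bp, pileups from 66 to 95 fragments and fold enrichments from 14.3 to 18.6. Their nearest untreated regions lay from 3.16 to 37707 kb away. The highest lay on chromosome Y at 58862533 to 58862917 (fold enrichment 18.6), and 2 more lay on the same chromosome at 58827155 to 58827536 (16.2) and 58855883 to 58856262 (14.6). The local background of these chromosome Y regions was 3.58 fragments, the genome-wide level and the lowest in the MST-312 list. Their fold enrichment thus rests on that floor and not on input measured around them. The others were on chromosome 18 at 7733716 to 7734144 (16.5), chromosome 5 at 111922165 to 111922894 (15.8), chromosome 11 at 10066020 to 10066573 (15.3), chromosome 4 at 102477944 to 102478438 (14.3) and chromosome 2 at 131548859 to 131549602 (14.3).

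Among chromosomes 1 to 22 and X, the share of MYC regions called in both libraries differed. Chromosome Y, with 1 untreated and 6 MST-312 regions, is left out of this ranking because of its few regions. Among untreated regions, the share with an MST-312 partner was highest on chromosome 17, at 59.6% (57.3 to 61.9), and lowest on chromosome X, at 42.7% (39.3 to 46.2). Among MST-312 regions, the share with an untreated partner was highest on chromosome 19, at 83.3% (81.3 to 85.2), followed by chromosomes 17 (77.6%), 22 (76.6%) and 16 (75.0%). It was lowest on chromosome 4, at 46.4% (43.5 to 49.2), followed by chromosomes 13 (49.6%), X (49.9%) and 18 (51.4%). The number of regions differed most, as a percentage and again without chromosome Y, on chromosome 22, with 856 untreated and 628 MST-312 regions, and on chromosome 19, with 1881 and 1415. On chromosome 4 the MST-312 list held 1234 regions against 1191.

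**Figure D2:**
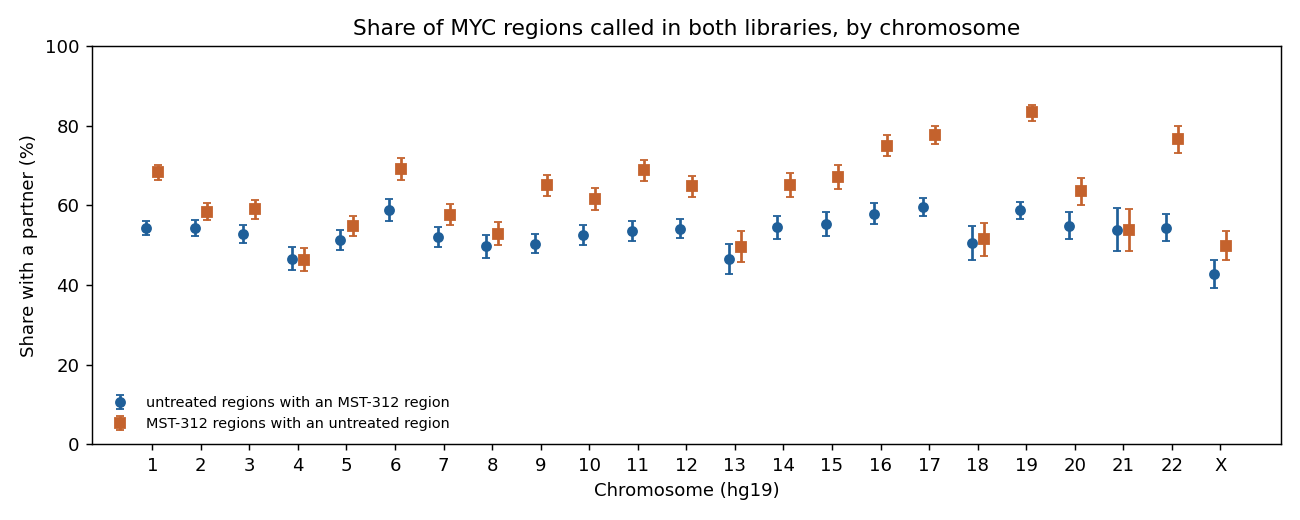
Share of regions (%) with a partner in the other list on each hg19 chromosome from 1 to 22 and X; blue circles are untreated regions, orange squares MST-312 regions, and bars are exact 95% intervals over regions. Untreated shares lie between 42.7% and 59.6%, while MST-312 shares range from 46.4% on chromosome 4 to 83.3% on chromosome 19.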

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

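Alternatives with a threshold of 26, a 1 kb gap or a limit on local background were chosen after seeing the data. With 1 library per condition, leaving out a replicate was not possible, and depth enters as kept tags only. A −log10 q of at least 10 removes no region, so its 8 values could not change. Of the 42 other alternative values, 16 stayed within the interval of the reported share or within 1.5 times the reported count or length, and 26 moved; the MST-312 list had fewer regions and less covered length than the untreated list under every threshold and merging rule run. The share of untreated regions with an MST-312 partner (53.6%) was 44.4% with at least 50% of both regions shared, 39.3% with summits within 100 bp, 58.0% with fold enrichment of at least 5, 59.3% with the top 27614 regions of each list by −log10 q, 58.4% with a 1 kb gap allowed, 59.5% with −log10 q of at least 26 in both lists and 82.0% with that threshold in the untreated list alone. The share of MST-312 regions with an untreated partner (63.3%) was 50.5%, 44.7%, 62.6%, 62.0%, 65.5%, 89.5% and 95.4% under the same settings, the last with the threshold in the MST-312 list alone. It stayed above the untreated share under each of the settings run. At −log10 q of at least 26 the lists held 16909 untreated and 11506 MST-312 regions, covering 19.5 and 11.5 Mb. With 4 equal parts in place of 10, the strongest part had partners for 96.5% of untreated and 96.3% of MST-312 regions, and the weakest MST-312 part for 57.8%. With strength ranked by −log10 q or pileup, the strongest MST-312 part reached 99.9% and 99.8%. The weakest untreated part had 10.5% and 6.15%, and the weakest MST-312 part 18.9% and 4.42%, against 70.1% by fold enrichment; the cause was not tested. Gene-based and E-box alternatives were not run. The gene lists fixed beforehand were not used.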

Other observations

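The tests on chromosomes, the checks of local background within strength parts and over 3 times the list median, and the rule for the 1 Mb windows were chosen only after their patterns were seen. Some parts of the genome held several MST-312 regions with few partners. In 12 windows of 1 Mb there were at least 10 MST-312 regions of which at most 1 had a partner, among 1015 windows with at least 10 MST-312 regions. Of these, 3 windows held 13 MST-312 regions each: chromosome 8 from 115 to 116 Mb, with 1 untreated region, chromosome 5 from 144 to 145 Mb, with 1, and chromosome 9 from 30 to 31 Mb, with 3. The 12 windows together held 135 MST-312 and 39 untreated regions, and the MST-312 regions in them were weak, with a median −log10 q of 15.1 and a median fold enrichment of 6.37. Over the whole MST-312 list, 18.9% to 32.2% of regions had a partner in the 3 weakest of 10 parts by −log10 q, and whether these windows exceed what a local gathering of weak calls would give was not tested. The mirror pattern, at least 10 untreated regions of which at most 1 had a partner, occurred in 3 windows. These were chromosome 2 from 6 to 7 Mb, chromosome 8 from 130 to 131 Mb and chromosome X from 106 to 107 Mb. The number of windows with at least 10 untreated regions is not given here, so the 12 and the 3 cannot be compared.

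Untreated regions without an MST-312 partner were weighed against technical sources. A lower number of kept tags, by 8.89%, would lower −log10 q by about that share. Yet 18.0% (95% interval 17.4 to 18.6) of the 16909 untreated regions with −log10 q of at least 26 had no MST-312 partner. The bound for this share was 5%. It was written before the check, but the threshold of 26 was added after seeing the data. The mirror share was 4.65% of 11506 MST-312 regions. In the 15265 pairs of single regions, the median −log10 q was 61.7 in the untreated list and 33.9 in the MST-312 list. A general fall of that size could take untreated regions somewhat above 26 off the list. The 18.0% thus speaks only to the number of kept tags and does not mark a separate set of lost sites. Of the untreated regions without a partner, 20.9% (20.2 to 21.6) had −log10 q of at least 26, above the bound of 10%. After a general fall of that size, untreated regions somewhat above 26 could still end close to the lowest listed value or below it. This check therefore cannot exclude that the listing level accounts for them. Separately called flanks of kept sites account for few of the untreated regions without a partner. Of these regions, 10.5% (10.0 to 11.0) lay within 1 kb of an MST-312 region, far from the 50% that explanation needs. A lower complexity of the MST-312 library, with its redundant rate of 0.49 against 0.24, and a less efficient precipitation cannot be told apart from lower MYC occupancy after MST-312, because each condition is 1 library.

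MST-312 regions without an untreated partner had a median −log10 q of 15.4, against 17.4 for untreated regions without a partner. Of these MST-312 regions, 5.29% (4.86 to 5.74) had −log10 q of at least 26, below the bound of 10%. That threshold was added after seeing the data. Most of them may thus be calls close to the lowest listed value. Most untreated regions without a partner were also below 26. Reaching 26 was rarer in the MST-312 list as a whole, with 11506 of 27614 regions against 16909 of 31378 untreated. High local background from repeats or extra copies was not a trait of the MST-312 regions without a partner as a set. Their median background was 4.74 fragments against 7.91 for those with a partner, a ratio of 0.600 (0.596 to 0.600), where at least 1.5 was set beforehand. That bar was out of reach, since few listed regions had 1.5 times 7.91 fragments. They were 87 of 2762 in the weakest of 10 parts by −log10 q and 485 of 2761 in the strongest. Missing the bar therefore decides nothing. The direction is a description only, since at a given −log10 q a higher background goes with a higher pileup. By pileup, the share with a partner rose from 4.42% in the weakest MST-312 part to 99.8% in the strongest. The untreated list had the same direction, with medians of 6.75 without and 8.68 with a partner. In the weakest MST-312 part by −log10 q the medians were 4.41 without and 7.91 with a partner. Medians were lower without a partner in every part but the strongest, where 2 regions without a partner had a median of 253 against 8.78. Of the 10121 regions without a partner, 10 had a background over 3 times the list median, and the explanation stays open for these; without such regions in the MST-312 list the share with a partner was 63.3%. New binding after MST-312 and a shift in the base composition of the sequenced fragments both remain open and were not tested.

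The differences between chromosomes may follow from the mix of weak and strong regions. After weighting each chromosome to the same mix of strength by −log10 q, the range over chromosomes of the untreated share fell from 16.9 to 4.73 percentage points. This is a ratio of 0.280, with a bootstrap interval of 0.265 to 0.559 that reaches past the 0.5 needed. Bootstrap intervals of such a ratio can sit too high, since resampling regions adds noise that widens a range. Here 0.280 lies near the lower edge, so the interval does not measure the spread around it. The explanation was left undecided. In the MST-312 list the range fell from 37.0 to 24.0 percentage points, a ratio of 0.649 (0.599 to 0.733). This lies above 0.5, but the interval has the same limit. On chromosome 19, with the highest share, the mix of strength gave 71.3% against 83.3% (81.3 to 85.2) found. On chromosome 4, with the lowest, it gave 56.2% against 46.4% (43.5 to 49.2). Strength by this measure is thus argued against as the whole cause on these 2 chromosomes. With strength by fold enrichment instead, the 2 ratios were 0.713 and 0.825, so the fall in the untreated list depends on the measure. After weighting by −log10 q, the MST-312 share was still 78.2% on chromosome 19 and 54.2% on chromosome 4. Base composition and gene density of the chromosomes were not examined here, and an effect of MST-312 that differs along the genome was not tested.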
